A study of Escherichia coli with 4 samples.

How the data were processed

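RNA of Escherichia coli cultures was sequenced from 4 samples, each a group of its own with 1 library. The submitters named strain BL21(DE3) for pET_28a, and strain MG1655 for HU_A, HU_WT and HU_A_22. Per the labels, every culture received 0.5 mM IPTG, an inducer of lac-controlled promoters, for 16 h, RNA was taken with Trizol, messenger RNA was selected on poly-T beads and the libraries were primed with random hexamers. The design text names HU-K22Q and HU-ΔA strains, an empty pET-28a vector and HDAH overexpression. The labels do not say which HU code stands for which of these strains, and their genotype field reads WT for all 4 samples, so the groups are called by their codes here.

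Gene-level tables of 3 comparisons were analysed: HDAH against pET_28a, HU_A against HU_WT and HU_A_22 against HU_WT. Per the submitters' processing notes, CASAVA, fastp, featureCounts 1.5.0-p3 and DESeq2 1.20.0 were used; the aligner and the BL21(DE3) genome build are not given in the sources used here. Per the file headers, the tables hold raw read counts per gene. A deposited signal column holds the same counts scaled by nearly 1 factor per library. FPKM values, scaled by gene length and library size, were also made by the authors. The log2 fold changes and the p-values, with p-values adjusted over the table, are the authors' deposited values for each comparison. In the HDAH comparison 3 columns of per-library values carry a name that matches no sample of the series; they were used in no step, so that comparison rests on the authors' fold changes and p-values and on the pET_28a column alone. Each list or table value derived from them is named as coming from the authors' deposited table.

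The HU tables gave 4422 genes in all, 4340 of them in both; HU_WT reads were equal in both tables for all 4340. All 4422 gene identifiers matched the MG1655 reference annotation ASM584v2, 4406 with the same symbol and 4421 with the same start and end, so coordinates are given in that assembly. No coordinates are given for the HDAH table, in which 3810 of 4301 genes had a symbol and 491 a locus tag alone. A filter on protein-coding genes removed nothing, because each gene carries that class in the files, rRNA genes included.

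A call is an adjusted p-value below 0.05 in the authors' deposited table, with the sign of its fold change. To learn what these p-values measure, the read counts were tested again with edgeR 4.0.16 (exact test, trimmed mean of M-values scaling) in R 4.3.3. At an assumed dispersion of 0.04, a coefficient of variation of 20%, all 342 HU_A calls and all 601 HU_A_22 calls were recovered. The log10 p differed by at most 0.0448 in HU_A_22 against HU_WT and by 0 in HU_A against HU_WT. The submitters' notes name DESeq2, and no replicate entered either side. For the HDAH table the same could not be run; there, other dispersions were tried by altering the variances implied by the authors' fold changes and p-values, followed by a two-sided normal test. The 5th percentile of the standard errors implied by its fold changes and p-values was 0.423, against 0.414 in HU_A and 0.415 in HU_A_22. A call therefore compares 2 libraries under an assumed spread; it does not compare conditions, and no difference reported here has a replicate check.

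For the HU comparisons, folds were computed from the read counts over effective library sizes, with exact conditional binomial 95% intervals. A gene at 0 reads in 1 library was set to a floor of 3 reads and its fold given as a lower bound; with 1 to 3 reads the ratio and its interval are given. Reads are not independent molecules, so intervals and floors cover counting error only. Standard errors for the difference between the effects in HU_A_22 and HU_A were implied from the authors' p-values. They were added as if independent, tested with a two-sided normal test and adjusted by the Benjamini-Hochberg method over 4340 genes.

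Gene lists, 36 in number, were fixed before the data were examined. For each list of at least 4 measured genes, the mean log2 fold change was set against 10000 random lists of the same size matched on level in 10 bins, and the two-sided share of random lists as extreme was adjusted over all lists of the 3 comparisons, and separately for the difference. A list is said to stand apart when that adjusted share is below 0.05. Because each group has 1 library, the shares and the percentile of the list's median among the random lists describe these libraries and are no test of conditions; the design set before the data were examined had called them p-values. Neighbouring genes of an operon move together, so the same mean was also set against all circular shifts of the gene order, and the adjusted share from these is given where it ended the call. In the HU comparisons the shifts included rRNA genes and the unread stretches described below, whose extreme values can widen their range. They were not rerun without these genes, so a lost call does not show that neighbouring genes account for a list's movement. Overlaps of calls were set beside the number of independent lists, and for the HU pair beside 100 simulated draws of unchanged groups sharing HU_WT.

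The genes named in the text follow a rule made before the data were examined: hupA and hupB; per comparison the 10 highest and 10 lowest called genes with a symbol, ranked by the implied 95% bound nearest to 0; up to 4 members of each list that stands apart; up to 4 called members of the TCA cycle, glyoxylate shunt, acetate, glycolysis and protein acetylation lists; and for the difference the 8 highest and 8 lowest. Other genes were chosen after their values were seen, which is said where they appear.

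The steps were tested on simulated counts for 4340 genes with 200 changed genes, each with at least 10 expected reads. Counts were drawn at a dispersion of 0.04 and tested with a normal test that assumed the same value. The recovered shares therefore hold only if that spread is true, and the exact test itself was not simulated. For HU_A_22 against HU_WT, 18.7% of genes changed by 1 on the log2 scale were recovered and 77.0% of those changed by 2. For HU_A_22 minus HU_A, the shares were 1.4% and 39.5%. Alternatives were stricter thresholds, level filters, pseudocounts, the signed z as list statistic, circular shifts and overlap rules, set before the data were examined, and other dispersions, scalings, gene sets, the list median and the direct exact test, added afterwards. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used, and DESeq2 1.42.0 for its size factors.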

Results

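The transcriptomes of 4 Escherichia coli cultures were compared through gene-level read counts and the authors' comparison tables. BL21(DE3), an expression strain that carries the T7 RNA polymerase gene, held the pET_28a vector or overexpressed HDAH. The submitters named MG1655, a K-12 laboratory strain, as the strain of HU_WT, HU_A and HU_A_22. These codes refer to HU, a DNA-binding protein of the bacterial nucleoid made of the HupA and HupB subunits. Every group had 1 library, so no spread between replicates could be measured. The count totals were 1617604 reads in pET_28a, 6434198 in HU_WT, 6494786 in HU_A and 6561007 in HU_A_22. The stable RNAs ssrA (tmRNA) and rnpB (RNase P RNA) together took 39.8% of reads in pET_28a (exact binomial 95% interval 39.8 to 39.9%), 51.4% in HU_WT (51.3 to 51.4%), 54.7% in HU_A (54.7 to 54.8%) and 51.1% in HU_A_22 (51.0 to 51.1%). Their shares moved in opposite directions in the MG1655 libraries: rnpB took 7.17% in HU_WT (7.15 to 7.19%), 15.9% in HU_A (15.8 to 15.9%) and 11.4% in HU_A_22 (11.39 to 11.44%), and ssrA 44.2% (44.16 to 44.23%), 38.9% (38.8 to 38.9%) and 39.7% (39.6 to 39.7%). The median gene had 115.0 reads in pET_28a, 111.0 in HU_WT, 97.0 in HU_A and 107.5 in HU_A_22.

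The HU genes were examined first. hupA (b4000, 4200281 to 4200553, plus strand) had 459 reads in HU_WT, 2 in HU_A and 417 in HU_A_22. It was 207-fold lower in HU_A than in HU_WT (95% counting interval 57.1 to 1718), and in HU_A_22 the ratio of 1.08-fold lower had an interval from 0.941 to 1.23. A loss of hupA in HU_A would match the HU-ΔA strain named in the design, while HU_A_22 had hupA reads near those of HU_WT. Reads per gene do not show whether those of HU_A_22 came from the chromosome or from a plasmid. The labels do not link codes to strains, so the codes are kept. hupB (b0440, 461451 to 461723, plus strand) had 652, 1216 and 1547 reads in HU_WT, HU_A and HU_A_22. Its ratio to HU_WT was 2.06 in HU_A (1.87 to 2.27), which the authors' deposited table did not call, and it rose 2.43-fold in HU_A_22 (2.21 to 2.66), which it did. The pET_28a library had 182 reads of hupA and 878 of hupB.

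HDAH against pET_28a compares HDAH overexpression with the empty vector in BL21(DE3). The series title links HDAH to HU acetylation and metabolism. With this control and no replicates, an effect particular to HDAH cannot be told apart from that of overexpressing any protein. Nor can it be told apart from a difference in growth stage between cultures. Heat shock chaperones, ribosomal proteins, ATP synthase, glycolytic enzymes and a terminal oxidase of respiration rose in the authors' deposited table, and fewer genes were called lower than higher. Of 4301 genes that table called 731, with 668 higher and 63 lower in HDAH. The highest were ibpB at 136-fold and ibpA at 58.7-fold, small chaperones that bind aggregated protein, then dnaJ at 49.6-fold, yafD at 35.1-fold and clpB at 27.9-fold, according to the authors' deposited table. Of these, dnaJ and yafD rested on only 11 and 14 reads in pET_28a. The same ranking of the authors' deposited table went on with bssS at 18.3-fold, glpF (glycerol facilitator) at 17.9-fold, cydA at 17-fold, pspA at 16.1-fold and ybgE at 15.8-fold. hupA rose 3.37-fold and hupB 2.44-fold in the authors' deposited table.

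Of 35 lists with enough measured genes, 17 stood apart from random lists in HDAH against pET_28a, 14 higher and 3 lower, by fold changes of the authors' deposited table. In the heat shock and protein folding list 14 of 21 genes rose (19 adjusted over the list alone), with a median of 3.51-fold in the authors' deposited table, above all 10000 random lists. Among ribosomal proteins 46 of 54 rose and 1, rpmI, fell (49 and 2 adjusted over the list alone); the median was 5.34-fold, and rplI at 14.8-fold, rplB at 12-fold, rplD at 10.8-fold and rpsF at 10.1-fold led in the authors' deposited table. rpmI was named after its value was seen. In the list of RNA polymerase and translation factors 11 of 20 rose (12 adjusted over the list alone), with fusA (elongation factor G) at 11.3-fold and rpoA (RNA polymerase alpha subunit) at 7.50-fold in the authors' deposited table. Nucleoid-associated proteins rose in 10 of 14 cases (12 adjusted over the list alone), among them fis at 10.1-fold, hns at 6.77-fold, ihfB at 5.27-fold and dps at 4.85-fold in the authors' deposited table.

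Lists of energy metabolism moved the same way. Per the authors' deposited table, glycolysis and gluconeogenesis rose in 17 of 20 genes (17 adjusted over the list alone), with gapA (glyceraldehyde-3-phosphate dehydrogenase) at 9.89-fold, fbaA (aldolase) at 6.73-fold, eno (enolase) at 4.41-fold and pckA at 4.36-fold. NADH dehydrogenase and terminal oxidase genes rose in 19 of 24 cases (20 adjusted over the list alone), and cydB reached 11.6-fold, cydX 6.78-fold and nuoN 6.57-fold in the authors' deposited table; cydA, cydB and cydX encode the bd-type oxidase. ATP synthase rose in 8 of 9 genes (8 adjusted over the list alone), with atpC at 6.75-fold and atpA at 4.76-fold in the authors' deposited table. The phosphotransferase system, which imports and phosphorylates sugars, rose in 8 of 14 genes (12 adjusted over the list alone), with fruB at 11.6-fold, ptsH at 11.5-fold, fruK at 6.10-fold and ptsI at 5.81-fold in the authors' deposited table. Fatty acid synthesis rose in 11 of 16 genes (11 adjusted over the list alone), with accC at 7.27-fold and fabG at 5.51-fold, and amino acid biosynthesis in 22 of 77 (25 adjusted over the list alone), with ilvC at 9.58-fold, in the authors' deposited table. In the TCA cycle 6 of 15 genes rose (8 adjusted over the list alone), with icd at 4.25-fold and mdh at 3.29-fold in the authors' deposited table. The glyoxylate shunt had 2 of 5 genes higher (4 adjusted over the list alone), aceB at 3.19-fold and glcB at 2.28-fold in the authors' deposited table. Acetate metabolism had 3 of 7 higher (3 higher and 1 lower adjusted over the list alone), ackA at 4.54-fold, an entry named pta at 2.92-fold and yjcH at 2.46-fold in the authors' deposited table. These 3 lists did not stand apart, and 0 of 7 protein acetylation and deacetylation genes were called in the authors' deposited table.

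Stress and iron genes completed the lists. Envelope stress genes rose in 9 of 22 cases (14 adjusted over the list alone), led by the phage shock genes pspA, pspB at 10.8-fold, pspD at 7.27-fold and pspC at 6.95-fold in the authors' deposited table. The general stress list of the sigma factor RpoS rose in 7 of 22 genes (12 adjusted over the list alone), with sra at 15.3-fold and elaB at 4.64-fold, and the oxidative stress list in 9 of 18 (11 adjusted over the list alone), with katG, a catalase, at 4.82-fold and ahpC at 4.17-fold in the authors' deposited table. Iron-sulfur cluster assembly rose in 9 of 15 genes (10 adjusted over the list alone) in the authors' deposited table, with iscS at 4.49-fold and iscR at 4.00-fold, and lost its call under circular shifts (adjusted share 0.0562). The lower lists rested on few calls in the authors' deposited table, and their counts adjusted over the list alone were equal. Iron acquisition held 2 genes that fell, fhuC by 2.67-fold and fepD by 2.34-fold, and 2 that rose, the storage genes ftnA and bfr, named after their values were seen; curli and biofilm matrix held csgE, 4.17-fold lower, and type 1 fimbriae 0 of 12, in the authors' deposited table. All 3 lost their calls under circular shifts, with adjusted shares of 0.143, 0.0806 and 0.231. Among single genes, the lowest included glnK at 4.6-fold lower, rnpB at 4.50-fold, rutB at 4.09-fold, zraP at 4.07-fold, hokD at 3.85-fold and rclC at 3.47-fold lower in the authors' deposited table. ybdZ, ydiT and ylcG were also among the lowest and rested on 9, 15 and 27 reads in pET_28a. Among the raised genes of the lists, fis and sra rested on 11 and 17 reads there. When the standard errors implied by the authors' deposited table were altered to a dispersion of 0.01 or 0.16, a normal test gave 1809 calls (1120 higher, 689 lower) and 88 calls (77 higher, 11 lower) in place of 731.

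**Figure D1:**
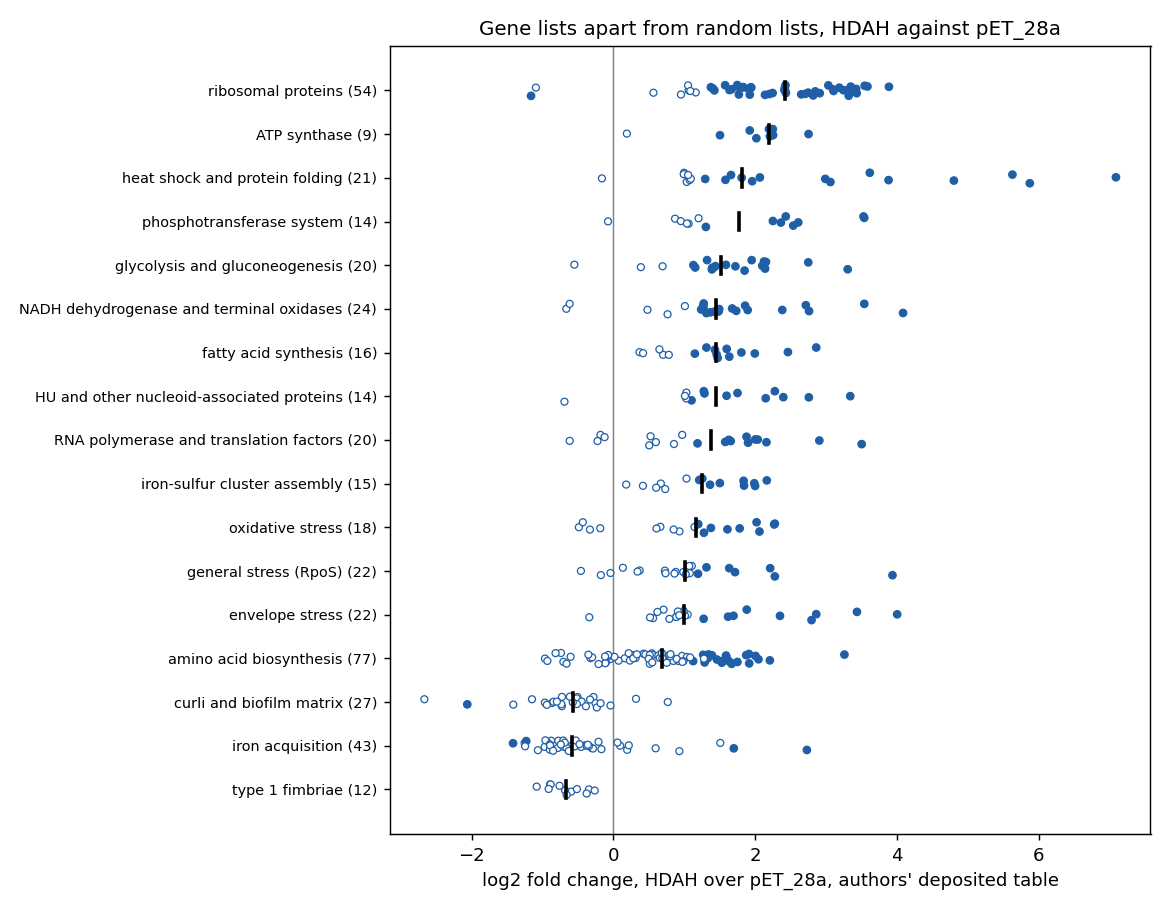
Log2 fold change of HDAH over pET_28a from the authors' deposited table (horizontal axis) for the genes of the 17 lists that stood apart from random lists, with the number of measured genes in brackets. Each point is a gene, filled where the table called it, and the black bar is the list's median; the ribosomal protein list has the highest median, 2.42 on the log2 scale, and ibpB lies farthest to the right.

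HU_A against HU_WT asks what changed with the strain coded HU_A. The number of calls and their larger direction depended on the assumed dispersion, as given in the section on processing. Acid resistance genes fell and purine synthesis genes rose, and a block of genes that had no reads in HU_WT gave the highest ratios. Under circular shifts of the gene order the purine list still stood apart (adjusted share 0.0187) and the acid resistance list did not (0.0806). The authors' deposited table called 342 of 4379 genes, 148 higher and 194 lower in HU_A. Scaling by library totals moved the median log2 fold change of all genes by -0.16 and the calls to 110 higher and 247 lower; the smallest called log2 fold change, 1.22 in size, is beyond that shift. The 10 highest genes were mmuM (at least 350-fold higher), yagF, ykfB, yagJ, yagE, ykfA, mmuP, ykfC, insX and xynR (at least 29.9-fold higher), all with 0 reads in HU_WT. They lie in a stretch of 38 genes from thrW to intF (262871 to 297096) in which HU_WT had 2 reads, HU_A 3192 and HU_A_22 4300. Further stretches from araD to araB (65855 to 70048), rhaM to rhaB (4093124 to 4097448) and valU to valY (2520931 to 2521248) had 0, 0 and 1 reads in HU_WT, against 121, 66 and 48 in HU_A. These stretches, noticed after the values were seen, hold 28 of the 148 higher calls. Their genes may be absent from the HU_WT genome or silenced there, which these libraries cannot tell apart. If they are absent, HU_WT differs in background from HU_A and HU_A_22, which would bear on both HU comparisons. Apart from hupA, the lowest genes were rRNA genes such as rrsG (974 reads in HU_WT, 1 in HU_A, 880-fold lower, 158 to 34803) and rrsD (at least 73.5-fold lower). rRNA took 0.0445% of reads in HU_WT (0.0429 to 0.0461%) and 0.000216% in HU_A (0.000118 to 0.000362%). The copies are near-identical, so values of single rRNA genes are uncertain. Their summed share fell too, which near-identity does not explain. Per the labels messenger RNA was selected before sequencing, yet ssrA and rnpB together took 51.4% of reads in HU_WT and 54.7% in HU_A. Whether rRNA was removed alike in each library is not known. The few rRNA reads left may therefore not reflect rRNA levels in the cells. The rRNA lists of the HU comparisons carry the same limit. Without the stretches and rRNA genes 300 calls were left, 120 higher and 180 lower.

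Of 36 lists, 8 stood apart in HU_A against HU_WT, 5 higher and 3 lower. Purine and pyrimidine synthesis rose in 12 of 26 genes (13 adjusted over the list alone), with a median of 2.04-fold in the authors' deposited table, above all 10000 random lists; purL rose 13.6-fold (12.2 to 15.1), purT 15.5-fold (8.83 to 29.7), purD 7.47-fold (6.31 to 8.91) and purK 7.28-fold (6.05 to 8.81). In the glutamate-dependent acid resistance list 12 of 14 genes fell (12 adjusted over the list alone), among them the regulator gadX by 5.17-fold (4.56 to 5.87), gadW 4.35-fold (3.52 to 5.41), slp 4.22-fold (3.91 to 4.56) and hdeD 3.40-fold (3.19 to 3.62). Ribosomal proteins rose in 14 of 54 genes (19 adjusted over the list alone), with rpsR 4.30-fold (3.65 to 5.10) and rpsQ 3.83-fold higher (3.38 to 4.35), and ATP synthase in 3 of 9 (6 adjusted over the list alone), with atpC 4.28-fold (4.01 to 4.57) and atpD 3.29-fold higher (3.11 to 3.48); the adjusted shares under circular shifts were 0.0562 and 0.231. Iron acquisition rose in 6 of 43 genes (11 adjusted over the list alone), with the enterobactin genes entC at 5.28-fold (2.87 to 10.5) and entE at 3.99-fold higher (2.77 to 5.88), and an adjusted share of 0.0959 under circular shifts. The general stress list held 3 of 24 genes that fell (3 adjusted over the list alone), osmY by 4.33-fold (3.94 to 4.77), aidB by 2.58-fold (2.42 to 2.74) and wrbA by 2.41-fold (2.22 to 2.61), and lost its call under circular shifts (0.325). Carbohydrate uptake and use had 9 of 74 genes higher and 2 lower (10 and 3 adjusted over the list alone). Higher were, for example, galT at 5.85-fold (4.81 to 7.16) and fucO at 4.76-fold (3.77 to 6.07), and lower were rbsD and rbsA, named after their values were seen; the list's adjusted share was 0.119 under circular shifts and 0.171 without the stretches, lac and rRNA genes. The rRNA list fell in 14 of 15 genes (14 adjusted over the list alone), with a median of -5.50 on the log2 scale when genes at 0 reads stand at their bound. Nucleoid-associated proteins did not stand apart (adjusted share 0.055, 0.0183 without the stretches, lac and rRNA genes, and 0.241 under circular shifts of all genes); of 15 genes hupA, hns and hha fell and fis rose (3 lower and 2 higher adjusted over the list alone). hns, hha and fis were named after their values were seen. The list's mean log2 fold change of -0.778 includes hupA at -7.61, and its median was -0.0678. The list was not rerun without hupA, so the share of 0.0183 shows no shift of the other members as a set. In the metabolic lists named in advance, pta (phosphotransacetylase) rose 3.05-fold (2.77 to 3.36), and 0 of 17 TCA cycle, 0 of 5 glyoxylate shunt, 0 of 20 glycolysis and 0 of 8 protein acetylation genes were called.

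HU_A_22 against HU_WT asks the same of the strain coded HU_A_22. Here too the number of calls and their larger direction depended on the assumed dispersion. Acid resistance and general stress genes fell, and genes of purine synthesis, fatty acid degradation and the lac operon rose. Under circular shifts the fatty acid degradation list lost its call (adjusted share 0.143). The authors' deposited table called 601 of 4383 genes, 294 higher and 307 lower in HU_A_22. The highest was lacZ, beta-galactosidase (b0344, 363231 to 366305, minus strand), with 44947 reads against 5 in HU_WT, 9191-fold higher (3938 to 28308). lacY, the lactose permease, had 3905 reads against 3 (1331-fold higher, 455 to 6456). lacA had 1059 against 2 (541-fold higher, 150 to 4476). lacI, the lac repressor gene, had 13065 reads against 225, 59.4-fold higher (52.0 to 68.0). In HU_A, lacZ was also called higher, with 43 reads (9.52-fold, 3.78 to 30.8), and lacI, with 246 reads, was not called. The remaining highest genes had 0 reads in HU_WT, with mmuM at least 425-fold higher and yagF, ykfB, yagJ, yagE, ykfA, intF and valX at least 51.1-fold. The stretches without reads in HU_WT hold 30 of the 294 higher calls. As in HU_A, their ratios may reflect the background of HU_WT. The 10 lowest were rRNA genes, such as rrsG at least 318-fold lower, with the same uncertainty as above. Without the stretches and rRNA genes 557 calls were left, 264 higher and 293 lower.

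Of 36 lists, 7 stood apart in HU_A_22 against HU_WT, 4 higher and 3 lower. Glutamate-dependent acid resistance fell in 13 of 14 genes (13 adjusted over the list alone), with a median of 20.5-fold lower in the authors' deposited table, below all 10000 random lists. hdeD fell 33.5-fold (28.2 to 40.2), the glutamate antiporter gene gadC 29.5-fold (26.8 to 32.6), the activator gadE 29.4-fold (25 to 34.7) and the acid chaperone hdeA 28.2-fold (25.9 to 30.7). General stress genes fell in 16 of 24 cases (16 adjusted over the list alone), with aidB 12-fold (10.7 to 13.5), osmY 6.43-fold (5.77 to 7.19), otsB 5.95-fold (5.43 to 6.54) and wrbA 5.58-fold lower (5.01 to 6.24). Purine and pyrimidine synthesis rose in 13 of 26 genes (14 adjusted over the list alone), with purL 11-fold (9.90 to 12.3), purT 11.7-fold (6.65 to 22.5) and purM 6.92-fold higher (5.55 to 8.71). Fatty acid degradation rose in 7 of 10 genes (8 higher and 1 lower adjusted over the list alone), with the transporter fadL 6.86-fold (6.03 to 7.83), fadE 5.85-fold (5.63 to 6.08), fadH 5.26-fold (5.03 to 5.51) and fadI 3.31-fold higher (3.14 to 3.50). Carbohydrate uptake and use had 20 of 74 genes higher, the lac genes among them, and 2 lower, xylB and rbsD, named after their values were seen (21 and 2 adjusted over the list alone). Without the stretches, lac and rRNA genes 14 of 68 were higher and 2 lower, with an adjusted share of 0.00739. Ribosomal proteins rose in 8 of 54 genes (8 adjusted over the list alone), with rpmH 5.15-fold higher (4.51 to 5.91) and an adjusted share of 0.188 under circular shifts. The rRNA list fell in 14 of 14 genes (14 adjusted over the list alone), with a median of -5.37 on the log2 scale when genes at 0 reads stand at their bound.

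Some lists of central metabolism held many calls in HU_A_22 without standing apart. In the TCA cycle 7 of 17 genes rose (7 adjusted over the list alone), with acnB (aconitase) 3.49-fold (3.36 to 3.62), sdhB 3.48-fold (3.30 to 3.68), fumA 3.30-fold (3.10 to 3.50) and sdhC 3.25-fold higher (3.07 to 3.44); the adjusted share was 0.0727, 0.0147 without the stretches, lac and rRNA genes, and 0.188 under circular shifts of all genes. ATP synthase rose in 8 of 9 genes (8 adjusted over the list alone), with adjusted shares of 0.060, 0.00869 and 0.219 in that order. Of 6 acetate metabolism genes 4 rose and 1 fell (4 and 1 adjusted over the list alone), with acs (acetyl-CoA synthetase) 2.93-fold higher (2.74 to 3.13), pta 2.79-fold higher (2.53 to 3.07), yjcH 3.11-fold higher (2.20 to 4.48) and poxB (pyruvate oxidase) 3.63-fold lower (3.28 to 4.03). Of 20 glycolysis and gluconeogenesis genes pck rose 2.46-fold (2.32 to 2.61) and tpiA fell 2.42-fold (2.21 to 2.65); adjusted over the list alone, 3 rose and 2 fell. No glyoxylate shunt gene (0 of 5) and no protein acetylation gene (0 of 8) was called. Leaving out the stretches, lac and rRNA genes also brought in iron acquisition (adjusted share 0.0667, then 0.00276, and 0.231 under circular shifts of all genes), in which 5 of 43 genes rose and 1 fell (5 and 1 adjusted over the list alone). It brought in iron-sulfur cluster assembly as well (0.152, then 0.0461, and 0.374 under circular shifts), in which sufA, sufB, sufC and sufD, named after their values were seen, fell (5 of 15 adjusted over the list alone).

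**Figure D2:**
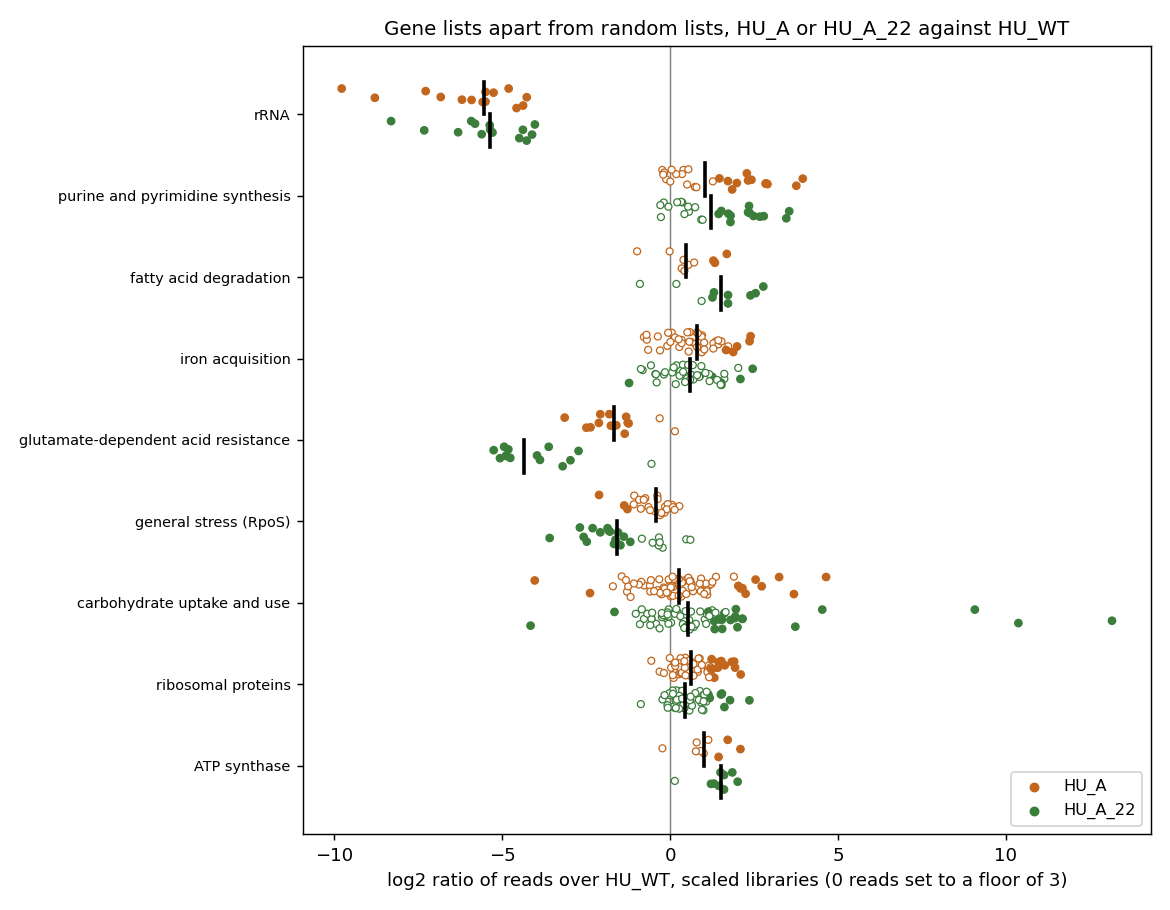
Log2 ratio of reads over HU_WT (horizontal axis) for the genes of each list that stood apart in HU_A or HU_A_22, with genes at 0 reads in 1 library set to a floor of 3 reads. Each point is a gene, filled where the authors' deposited table called it, and the black bar is the median of the plotted genes; in the acid resistance list the HU_A_22 points lie below those of HU_A.

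**Figure D3:**
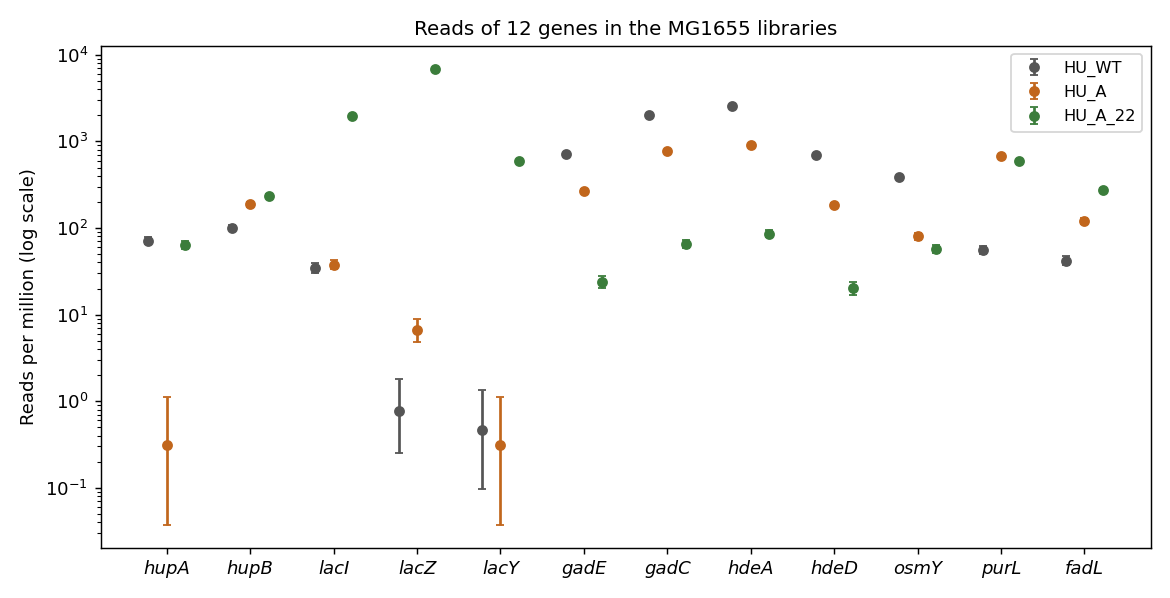
Reads scaled to the library total (log axis) for 12 genes in the 3 MG1655 libraries, with exact binomial 95% intervals that cover counting error only. hupA is low in HU_A alone (2 reads), lacI, lacZ and lacY are high in HU_A_22, and gadE, gadC, hdeA and hdeD step down from HU_WT to HU_A and HU_A_22.

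The difference between the effects in HU_A_22 and HU_A was tested per gene, and 21 of 4340 genes passed, 10 higher and 11 lower in HU_A_22. By reads of HU_A_22 over HU_A, lacZ was 969-fold higher (719 to 1339), hupA 193-fold (53.2 to 1601), lacY 1810-fold (501 to 14953), lacI 49.2-fold (43.4 to 56.1), melA (alpha-galactosidase) 9.84-fold (7.74 to 12.7), zntA (zinc exporter) 7.67-fold (7.30 to 8.06) and yaiY 7.36-fold higher (5.89 to 9.30). rrlC also passed, on 5 reads against 0. Genes of acid resistance made up most of those lower in HU_A_22: gadC was 12.5-fold lower (11.3 to 13.8), gadE 12.2-fold (10.4 to 14.5), hdeA 11.3-fold (10.4 to 12.4), hdeD 9.84-fold (8.21 to 11.9), hdeB 8.91-fold (7.74 to 10.3), gadB 8.75-fold (4.36 to 19.9) and yhiD 7.06-fold (3.72 to 14.8), beside the small RNA arrS at 13.4-fold lower (9.58 to 19.3). Of the 36 lists 5 stood apart for this difference. Glutamate-dependent acid resistance had a median log2 difference of -2.20 with 7 of 14 genes passing, and the general stress list one of -1.08 with 0 of 24 passing. Fermentation and anaerobic respiration had a median of -0.41 and an adjusted share of 0.129 under circular shifts, and carbohydrate uptake and use one of 0.22, with lacZ and lacY as its passing genes. The rRNA list was among the 5, but 7 of its 15 genes in HU_A and 11 of 14 in HU_A_22 were at 0 reads in 1 library, so its difference has no meaning. Without the stretches, lac and rRNA genes the carbohydrate list no longer stood apart (adjusted share 0.142), and the TCA cycle (median 0.68), fatty acid degradation (median 0.96) and nucleoid-associated proteins (median 0.05, with hupA as the passing gene) did, with 0 of 17, 0 of 10 and 1 of 15 genes passing. Under circular shifts of all genes these 3 lists did not stand apart (adjusted shares 0.157, 0.150 and 0.150). The nucleoid list's mean log2 difference of 0.647 includes hupA at 7.51. That list was not rerun without hupA, so it shows no shift of the other nucleoid protein genes as a set. An exact test of the 2 libraries against each other at a dispersion of 0.04 called 76 genes, 20 of the 21 among them.

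Calls overlapped between the HU comparisons, which share the HU_WT library. In both, 121 genes were higher (10 if the lists were independent) and 146 lower (13.7 if independent), and 0 were called in opposite directions (23.6 if independent). Across 4340 genes, which are not independent replicates, Pearson's r of the authors' log2 fold changes was 0.786 and Spearman's rho 0.720, against 0.500 and 0.472 simulated for unchanged groups sharing HU_WT. The covariance was 2.04 against a simulated 0.214. Without the stretches and rRNA genes the covariance was 1.17 and r 0.681, and 226 genes were called in the same direction in both. With 1 control library, part of the excess may come from that library. The purine and pyrimidine synthesis list, higher in HU_A and in HU_A_22, had a median log2 difference between them of -0.0106. Its interquartile range ran from -0.208 to 0.170, so HU_WT alone stays possible as the source of that rise. HDAH and HU_A shared 42 higher genes (19.6 if independent) and 0 lower (1.85 if independent), while 26 were called in opposite directions (28.2 if independent); HDAH and HU_A_22 shared 65 higher (39.6 if independent) and 2 lower (3.14 if independent), and 45 went opposite ways (47.1 if independent). In those pairs r across genes was 0.0853 and 0.100.

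**Figure D4:**
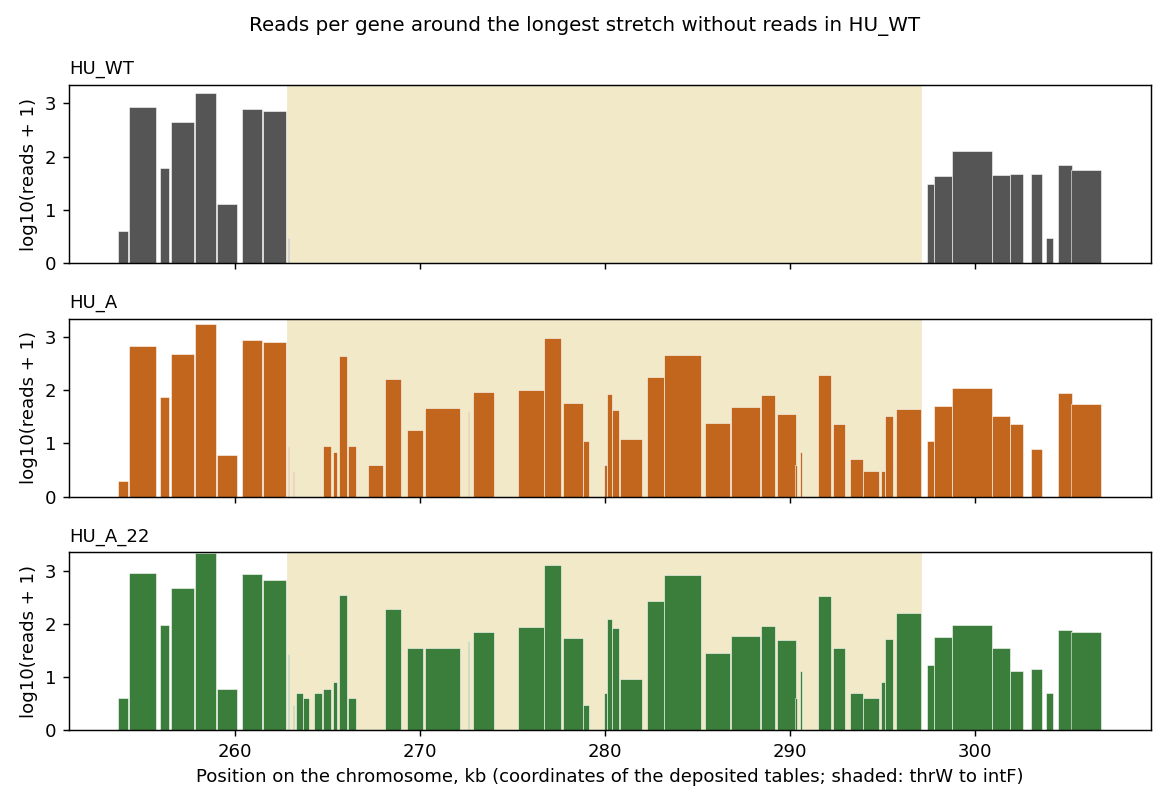
Log10 of reads plus 1 per gene (vertical axis) along the MG1655 chromosome in kilobases from thrW to intF (shaded) and 9 kb on each side, in the 3 MG1655 libraries. Each bar spans a gene; HU_WT has 2 reads over the 38 shaded genes, HU_A 3192 and HU_A_22 4300.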

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

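The test of the difference between HU_A_22 and HU_A was set before the data were examined; the tests of explanations in this part were all chosen after the results they weigh had been seen. The log2 fold change against HU_WT differed between HU_A_22 and HU_A for 21 genes. The log2 difference, HU_A_22 minus HU_A, was 10.74 for lacY, 9.91 for lacZ, 7.51 for hupA, 5.62 for lacI, 3.29 for melA, 2.93 for zntA and 2.87 for yaiY. It was -3.75 for arrS, -3.65 for gadC, -3.61 for gadE, -3.51 for hdeA, -3.30 for hdeD, -3.16 for hdeB, -3.12 for gadB and -2.81 for yhiD. For rrlC, an rRNA gene with near-identical copies, the fitted value of 5.32 is no measure of size: with 5 reads in HU_A_22 and 0 in HU_A, the reads show at least 1.55-fold. The other 5 genes, named after their values were seen, were ycfJ and ryeA, higher in HU_A_22, and hyaC, yhiM and mdtF, lower.

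HU_WT lacked reads over 4 stretches that were read in HU_A and HU_A_22, the longest from thrW to intF. Too few reads in HU_WT are excluded, since 3532 reads would be expected over the longest stretch at the rate of HU_A and 2 were seen. Absence of the stretches from the HU_WT genome and silencing cannot be told apart, because reads at the floor allow any silencing above 1177-fold, and no DNA was sequenced here. The median log2 fold change of 40 flanking genes, -0.0534 in HU_A_22, decides nothing, since a stretch was defined to end where HU_WT had reads. Deletions of araBAD and rhaBAD exist in a commonly used K-12 derivative. If the strains differ in background, part of what separates both HU groups from HU_WT may come from it. The same limit covers the lacZ ratios to HU_WT: with 5 lacZ reads there, low expression and absence of the gene cannot be told apart.

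The lac genes and lacI were high in HU_A_22, and lacZ was also higher in HU_A than in HU_WT (43 reads against 5), with 246 and 225 reads of lacI. Fewer transcripts of the repressor gene are excluded, since lacI was 49.2-fold higher in HU_A_22 than in HU_A. A further copy of lacI, which many expression plasmids carry, is a candidate explanation for the lacI reads: its chromosomal neighbour mhpR was 2.48-fold higher, far below lacI. More repressor would not by itself raise lacZ. Per the labels all cultures received the inducer, yet lacZ, lacY and lacA had 5, 3 and 2 reads in HU_WT. In HU_A they had 43, 2 and 3 reads, with lacI at 246. Whether the inducer acted alike in all cultures therefore stays open. Whether the HU change itself acts on the lac genes stays open, because the 969-fold difference in lacZ stands on 1 library per group.

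Acid resistance genes were lower in HU_A and lower again in HU_A_22. The shared HU_WT library alone is excluded as the whole cause, since the list's median log2 difference between HU_A_22 and HU_A, in which HU_WT has no part, was -2.20, with an interquartile range from -3.27 to -1.61. Lower activity of the whole RpoS programme may contribute: the general stress list had a median log2 difference of -1.08, with an interquartile range from -1.26 to -0.43. rpoS itself had 12478 reads in HU_WT, 9425 in HU_A and 9646 in HU_A_22. A biological effect of the HU change and a difference in growth stage between single cultures both stay open and untested. So does whatever raised lacI and lacZ in HU_A_22, which cannot be told apart from the HU change in these libraries.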

How the results depend on the processing

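Alternative dispersions, scalings, gene sets, the list median and the direct exact test were chosen after the data were seen; the others were set before. Each call compares 2 libraries, so the assumed dispersion decides most counts, and no replicate could measure it. At a dispersion of 0.01 the calls numbered 1809 in HDAH, of which 1120 (61.9%) were higher, against 91.4% in the authors' deposited table. They numbered 1115 in HU_A (522 higher, 593 lower) and 1449 in HU_A_22 (757 higher, 692 lower). At 0.16 they numbered 88 (77 higher), 53 (30 higher, 23 lower) and 93 (41 higher, 52 lower). So the larger direction changed in HU_A at 0.16 and in HU_A_22 at 0.01; the cause was not tested. At an adjusted p below 0.01, fewer by construction, there were 211 in HU_A and 395 in HU_A_22, and shared calls were 173 for HU_A and HU_A_22, 24 for HDAH and HU_A and 38 for HDAH and HU_A_22. The difference between HU_A_22 and HU_A gave 76 genes with a covariance of 0.5 times the product of the standard errors, which narrows the error by construction, and 76 with a direct exact test at 0.04, 487 at 0.01 and 5 at 0.16. Lists standing apart fell from 8 to 2 in HU_A under circular shifts, and rose from 7 to 14 in HU_A_22 with the median and to 13 with the signed z; the cause was not tested.

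Of the other counts, 12 under alternatives set before and 17 under added ones stayed within 1.5 times the reported count. A further 12 could not move and test nothing: a minimum log2 fold of 1 lies below the smallest called one, the recomputed Benjamini-Hochberg adjustment is the authors' own, and the protein-coding filter removed no gene. Of the named folds with a counting interval, 67 stayed within it with a pseudocount of 1; with 5, 65 stayed and 2 moved. The 37 folds given as lower bounds stayed beyond their bound with a pseudocount of 1 and fell below it with 5, by construction, since 5 exceeds the floor of 3 reads. With either pseudocount 0 called folds changed sign. No paired analysis was possible because each group had 1 library; leaving out a replicate and replicated edgeR or DESeq2 fits could not be run for the same reason. Pseudocounts were not tried for HDAH, whose library matched no sample. Depth limits genes near the floor of 3 reads most.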

Other observations

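The genes in this part were chosen after their values were seen; the tests of distance from the replication origin were written before their results. Genes of the mraZ to murF cluster, which act in cell division and peptidoglycan synthesis, fell in both HU comparisons. These comparisons share the HU_WT library, so changes seen in both, here and in the next paragraph, may come from that library. mraZ was 7.52-fold lower in HU_A (6.30 to 9.04) and 5.62-fold lower in HU_A_22 (4.83 to 6.56), rsmH 6.93-fold (6.01 to 8.02) and 6.13-fold lower (5.38 to 7.01), and murE 5.71-fold (5.11 to 6.40) and 6.2-fold lower (5.54 to 6.95). In the authors' deposited table for HDAH, mraZ, rsmH and murE rose by 1.18, 2.20 and 1.74 on the log2 scale. The phage shock gene pspA was 5.39-fold lower in HU_A (5.14 to 5.66) and 3.85-fold lower in HU_A_22 (3.70 to 4.01), and hns, a nucleoid protein gene, 6.37-fold (5.84 to 6.97) and 4.37-fold lower (4.07 to 4.70). fis, another nucleoid protein gene, rose 4.46-fold (3.57 to 5.62) and 4.62-fold (3.71 to 5.80).

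The hydrogenase genes hyaA to hyaF and the nitrate reductase gene narG were called lower in both HU comparisons. hyaA was 4.58-fold lower in HU_A (4.24 to 4.95) and 15.5-fold lower in HU_A_22 (13.7 to 17.7), and narG 2.48-fold (2.25 to 2.74) and 6.83-fold lower (5.92 to 7.92). yafD rose 17.5-fold in HU_A (14.4 to 21.4) and 19.1-fold in HU_A_22 (15.8 to 23.4), and dnaJ 8.56-fold (7.40 to 9.95) and 6.37-fold (5.50 to 7.42).

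The hypothesis that fold changes follow distance from the replication origin was tested by Spearman's rho across genes, which are not independent replicates, in 2 relations. In HU_A rho was -0.0637, within the range of circular shifts of the gene order (share of shifts as large 0.213). In HU_A_22 rho was -0.0525, just beyond it (share 0.0234, adjusted 0.0468), so a weak relation may exist there and accounts for little of the spread.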
